A study of Homo sapiens with 7 samples.

How the data were processed

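MicroRNA levels were measured in cultured human fetal retinal pigment epithelial (RPE) cells on 7 single-colour Agilent human miRNA arrays (version 2.0 design), hybridised with Cy3-labelled total RNA extracted with Trizol, per the labels. The arrays held 719 human and 76 viral miRNAs, measured by 1 to 6 probes each, with 3 to 16 spots per probe and 13737 spots per array, of which 12784 carried miRNA probes. Per the file headers, all 7 arrays lay on 1 slide and had 1 scan time, so slide and scan could not be tested as batches. All differentiated arrays and dedifferentiated replicate 1 lay in slide row 1, and the partially differentiated array and dedifferentiated replicates 2 and 3 in row 2. Row thus partly followed group, and the partially differentiated array shared no row with the differentiated arrays.

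Images were read with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. The deposited scanner files gave spot intensity values: the processed signal, from which the program had already subtracted the background per the file headers, the median and background signals, and flags for spots well above background, saturated or outlying. A second deposited file per array gave the total intensity of each miRNA. The authors' value table held that total intensity multiplied by 1 factor per array. The ratio of each table value to the total signal was constant within an array to a relative spread of 3.92e-07. The values themselves showed how the factors were set: the sum of miR-130a and miR-24 was 1926.9 in every column of the authors' table, so the authors' scale held the mean of these 2 miRNAs constant. This rule was inferred from the values. The table was linear, without centring, and its direction was that of the signal; why these 2 miRNAs were used stays unknown. Its column medians were 0.0422, 0.339 and 0.102 for differentiated replicates 1 to 3, 0.268 for the partially differentiated sample, and 0.227, 0.106 and -0.109 for dedifferentiated replicates 1 to 3.

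Group and replicate were taken from the sample titles. The series text counts 3 biological replicates per condition, but the title of dedifferentiated replicate 3 calls it a technical replicate of dedifferentiated replicate 1. These 2 arrays were averaged on the log2 scale and counted as 1 sample, which left 3 differentiated, 1 partially differentiated and 2 dedifferentiated RNA samples. The technical pair correlated at r = 0.998 across the 216 miRNAs tested, with an SD of their log2 differences of 0.15, against 0.66 between the 2 dedifferentiated RNA samples. The labels do not say that the cultures came from separate donors, so p-values measure the spread between these samples, which may be technical. Few arrays limit the precision: the median SD within a group was 0.12 among differentiated and 0.20 among dedifferentiated samples on the log2 scale.

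The processed signal was averaged over the spots of a probe, leaving out outlier-flagged spots, and summed over the probes of a miRNA. A miRNA was detected on an array if at least 1 probe was well above background on most of its spots (a share above 0.5). Sums were divided by the array's 75th percentile over the 142 human miRNAs detected on all arrays. They were then raised to a floor, the median over arrays of the lowest scaled detected value (log2 of -5.84), and log2 was taken. A level of 0 is therefore the 75th percentile, and levels compare samples for 1 miRNA, not 1 miRNA with another. Saturated spots were kept: 2 miR-204 spots on the array of differentiated replicate 3 were saturated, and 0 miRNA spots on the other arrays. Viral and control probes stayed out of scaling and tests. Among the 78 called miRNAs with at least 2 probes detected on all arrays of both groups, 0 had a probe that changed in the opposite direction.

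The 216 human miRNAs detected on every array of at least 1 of the 2 main groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes), with 1 mean per group in a fit over all 6 RNA samples (residual df 3, prior df 1.91). Tests were two-sided with Benjamini-Hochberg adjustment, and the threshold was an adjusted p of 0.05. The lone partially differentiated sample was assumed to vary like the other groups. Where a called miRNA was not well above background on any array of 1 group, the change is given as a bound. Its p-value uses values that can lie at the floor, as for miR-9 and miR-424, each with an SD of 0 in the group at the floor. Such a p-value is partly set by the floor. The bright group's mean was set against the dim group's mean of, per array, the higher of the lowest detected signal and the miRNA's own signal; because this limit differs from the common floor, a bound can exceed the fitted fold. Gene lists were tested with camera (preset and estimated correlation) and fry for the 10 of 22 fixed lists with at least 5 tested members. Of 252 list entries, 250 matched a name on the array, and miR-106a and miR-519a were not analysed here.

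Test, lists, the rule for named miRNAs and all alternatives except 3 (normexp on median signals, the first slide row alone and scaling by the hur control probes) were fixed before the data were examined. Named were the 10 largest changes per direction among called miRNAs detected on every array of both groups whose groups did not overlap; the 5 brightest per direction among those given as bounds; up to 4 tested members per list, by mean level; and miR-204 and miR-211. miRNA names are those of the array design. Gene names and neighbours were taken from the NCBI RefSeq table of assembly GRCh38.p14, in which 205 of the 216 tested miRNAs matched a gene; strand was not considered. Near-identical family members (such as miR-204 and miR-211, the miR-376 group, or let-7) can share probe signal, which these arrays cannot separate.

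The limma step was tested on simulated data for dedifferentiated against differentiated samples over 216 miRNAs. Each of 20 draws held 60 changed miRNAs, with the differentiated means, the spreads fitted by limma and independent normal errors. The step called 91.0%, 97.0% and 99.8% of miRNAs changed by 1, 2 and 3 log2 units, and 1.57% of unchanged ones. The simulation held no floor, no scaling error of an array and no shift of a whole sample, so these rates can be too favourable for the real data. Alternatives covered the scaling, the authors' values, the signal, the combination of probes, the filter, the floor, the treatment of the technical replicate, the replicate number as a block, the moderation, the threshold and leaving out each array.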

Results

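The series profiled miRNAs in RPE cells, the pigmented monolayer behind the neural retina, to compare differentiated with dedifferentiated cultures. Differentiated cells had been kept on porous filters for weeks until they formed pigmented, hexagonal, epithelial sheets (3 samples). Dedifferentiated cells had crept out from the open border of a sheet, kept dividing and looked fibroblastic (2 RNA samples on 3 arrays). A single sample had a mixed epithelial and fibroblastic look and is called partially differentiated here. Between 174 and 221 of the 719 human miRNAs were detected per array. The total human miRNA signal was 223720, 252990 and 283400 on the differentiated arrays, 206310 on the partially differentiated array, and 108980, 98228 and 82289 on dedifferentiated arrays 1, 2 and 3. All log2 changes below are dedifferentiated minus differentiated unless stated, after scaling each array to its 75th percentile, with n = 3 differentiated and n = 2 dedifferentiated samples and limma standard errors (SE). The 4 other scalings gave lower median changes, so under them rises were mostly smaller and falls mostly larger than the values below.

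miR-204 and miR-211, 2 related miRNAs of the pigment epithelium, were lower in dedifferentiated cells. miR-204, encoded within the bounds of TRPM3 and abundant in pigment epithelium, fell by 2.28 ± 0.57 on the log2 scale (4.86-fold; adjusted p = 0.0175, limma); 2 of its spots on the array of differentiated replicate 3 were saturated. Its near-identical relative miR-211, encoded within TRPM1, fell by 3.15 ± 0.95 (8.87-fold; adjusted p = 0.0312). miR-204 gave 42.5%, 40.1% and 38.6% of the total human miRNA signal on the differentiated arrays, 29.1% on the partially differentiated array, and 5.19%, 17.1% and 5.21% on dedifferentiated arrays 1, 2 and 3. The 2 dedifferentiated RNA samples therefore differed widely for these miRNAs, with levels of 4.35 ± 1.35 for miR-204 and 1.18 ± 2.29 for miR-211 (log2, SD, n = 2), against 6.63 ± 0.15 and 4.33 ± 0.20 in differentiated samples (SD, n = 3). Leaving out any differentiated array ended both calls: the log2 change of miR-204 was -2.21, -2.30 and -2.34 with adjusted p = 0.103, 0.075 and 0.0748 without differentiated replicate 1, 2 and 3, and that of miR-211 was -3.04, -3.20 and -3.21 with adjusted p = 0.141, 0.113 and 0.117 (limma). On the authors' scale and without scaling, the log2 change of miR-204 was -3.12 and -3.48. After quantile normalization miR-211 had no call either (adjusted p = 0.116, limma). Over all 24 alternatives for these 2 miRNAs, the adjusted p ranged from 4.95e-05 to 0.182 for miR-204 and from 0.00019 to 0.264 for miR-211.

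miR-9 and its partner strand miR-9*, known from neural development, were well above background in all 3 differentiated samples and on no dedifferentiated array, which makes them at least 7.63-fold and 5.73-fold lower (adjusted p = 8.04e-05 and 0.000205, limma). Bounds were smaller for miR-361-3p, miR-342-5p and miR-139-3p, at least 1.90-fold, 1.86-fold and 1.79-fold lower. Among miRNAs detected on every array of both groups, miR-885-5p fell by 3.40 ± 0.74, miR-99a by 2.19 ± 0.30, miR-148b by 1.58 ± 0.36, miR-338-3p by 1.54 ± 0.30 and miR-125b by 1.53 ± 0.22. Leaving out any differentiated replicate ended the calls of miR-885-5p, miR-148b and miR-660, with adjusted p = 0.0747, 0.0854 and 0.0731 at most (limma). The call of miR-338-3p was lost without differentiated replicate 1 (adjusted p = 0.053) and that of miR-185 without replicate 1 or 3 (0.0681 and 0.0537). Smaller falls in this class were 1.46 ± 0.25 for miR-455-3p, 1.42 ± 0.30 for miR-660 and 1.42 ± 0.29 for miR-185. Several of these lie within the bounds of protein-coding genes: miR-885 in ATP2B2, miR-338 in AATK, miR-455 in COL27A1 and miR-660 in CLCN5.

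miR-31, miR-21, miR-424 and their partner strands miR-31* and miR-21* were among the miRNAs that rose. miR-31* and miR-31, the 2 strands of 1 precursor on chromosome 9, rose by 4.45 ± 0.13 and 4.24 ± 0.18 (21.9-fold and 18.9-fold; adjusted p = 5.71e-05 and 0.000110, limma). miR-21, often raised in proliferating and fibrotic tissue, rose by 2.62 ± 0.18 (6.15-fold, adjusted p = 0.000441, limma). Its partner strand miR-21* was below background on every differentiated array and at least 28.1-fold higher under the main scaling and its detection limits. The fitted change of miR-21* was 20.9-fold, and 3.54 on the log2 scale without scaling. miR-424 was likewise undetected in differentiated cells and at least 47.6-fold higher in dedifferentiated cells under the main scaling and its detection limits (adjusted p = 3.83e-05, limma). Its fitted log2 change ranged from 1.49 to 6.67 over 24 alternatives, with adjusted p from 1.34e-06 to 0.0128. miR-221, which targets the cell-cycle inhibitor p27, rose by 2.19 ± 0.14. miR-29b, which targets collagen transcripts, rose by 2.28 ± 0.34. Its partner strand miR-29b-1* was at least 8.39-fold higher under the same limits (fitted 5.70-fold, log2 change 1.82 without scaling). On the authors' scale and without scaling, the log2 change was 3.40 and 3.04 for miR-31, 1.78 and 1.42 for miR-21, 1.35 and 0.99 for miR-221, and 1.45 and 1.08 for miR-29b, all called. miR-193a-3p rose by 2.98 ± 0.24, miR-129-3p by 2.87 ± 0.33 and miR-630 by 2.75 ± 0.32. miR-137 and miR-191* were at least 9.23-fold and 3.15-fold higher under these limits, and neither was well above background in differentiated samples. For miR-137 the fitted change was 5.39-fold, and 1.84 on the log2 scale without scaling. For miR-191* the bound rested on its own signal, its log2 change was 0.82 on the authors' scale, and it had no call without scaling (0.45, adjusted p = 0.109, limma) and the opposite sign with normexp (-0.147, adjusted p = 0.851). The plot of levels by array shows these changes against the spread of the samples.

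**Figure D1:**
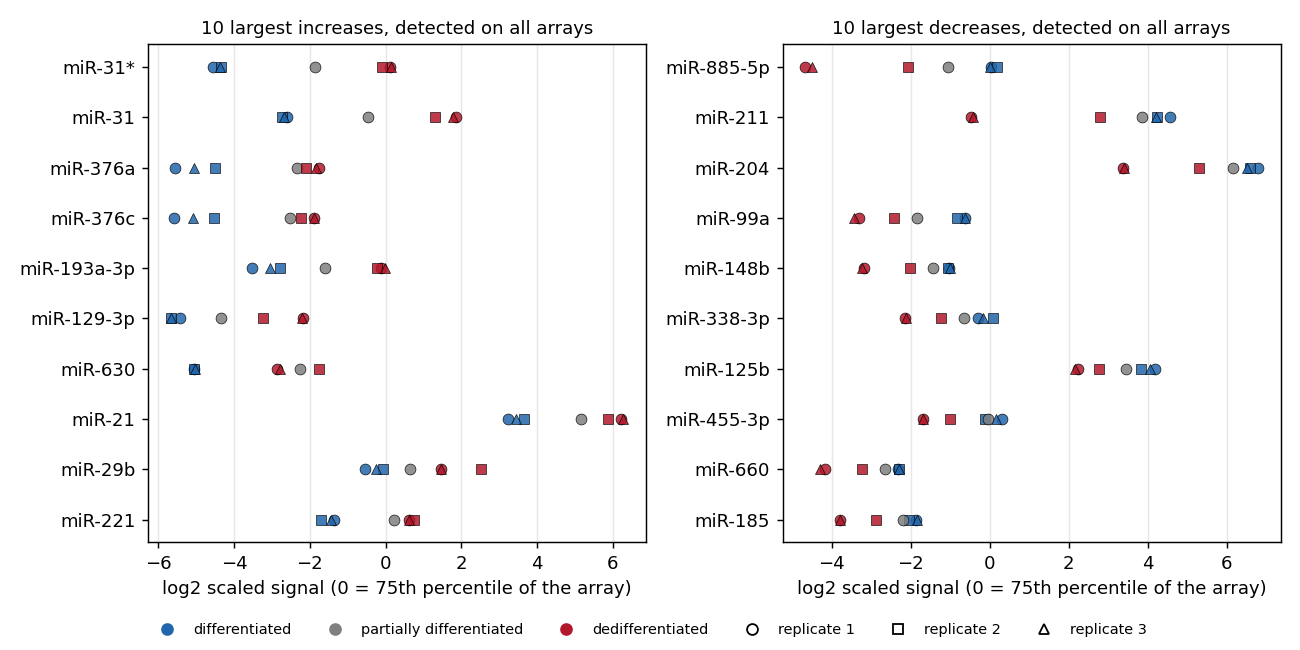
Level on each array (x axis, log2 scaled signal, 0 at the 75th percentile of the array) of the 10 miRNAs with the largest increase (left) and the 10 with the largest decrease (right) among those detected on all arrays of both groups; each point is 1 array, coloured by group and shaped by replicate number. The differentiated and dedifferentiated arrays do not overlap for any of the 20 miRNAs, by the rule that chose them, the technical pair (dedifferentiated 1 and 3) nearly coincides, and dedifferentiated 2 lies towards the differentiated arrays for the decreases, as for miR-204, whose dedifferentiated level was 4.35 ± 1.35 (SD, n = 2).

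Of the imprinted miRNA cluster on chromosome 14 (14q32), 54 members were on the array, 22 were detected on at least 1 array and 13 were tested. miR-127-3p, miR-136 and miR-377, each detected on 2 of the 3 differentiated arrays, were tested only because every dedifferentiated array detected them, which favours a rise. The mean differentiated level of miR-376b, miR-381, miR-410, miR-495 and miR-654-3p was the floor itself (-5.84). Their rises are therefore distances from the floor, and the group test partly rests on it. All 13 tested members of the cluster were called higher, with a median change of 1.88 (camera adjusted p = 0.000183), although the sign of miR-432 turned without scaling. With an estimated correlation between its members the group test was not past the threshold (adjusted p = 0.614), and fry, which asks only whether members move one way, gave an adjusted p of 0.00229. The leading members were miR-377 (3.15 ± 0.21; detected on 2 of the 3 differentiated arrays), miR-376a (3.10 ± 0.33) and miR-376c (3.00 ± 0.33). miR-494 rose by 1.21 ± 0.18, but was at 0.37 on the authors' scale (adjusted p = 0.128) and 0.0089 without scaling (adjusted p = 0.972, limma). 10 of the 13 kept their call under all 4 other scalings, and miR-432, miR-487b and miR-494 did not. Over the alternatives the median of the list ranged from 0.146 to 2.9 and the camera adjusted p from 2.01e-08 to 0.085. The highest p came with a floor 4 times higher, which lay above the mean differentiated level of every member tested except miR-494.

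Among miRNAs known to respond to TGF-beta, 5 of 7 tested were higher and 1 was lower, with a median change of 3.11, which is that of miR-155. The 5 were miR-21, miR-21*, miR-31, miR-424 and miR-155 (3.11 ± 0.18, a difference from the floor, where it lay on all 3 differentiated arrays, although detected on 1), while miR-181a fell by 0.86 ± 0.14. The group test was not past the threshold in the main scaling (camera adjusted p = 0.118; adjusted p = 0.614 with an estimated correlation) but was under the authors' scaling (adjusted p = 0.00328), and over all alternatives it ranged from 0.000475 to 0.300. Adjusted over the list alone, miR-181b (-0.37 ± 0.13) was a second lower member. Of the miR-181 family, 3 of 4 fell (miR-181c by 1.25 ± 0.22 and miR-181d by 0.69 ± 0.10), and 4 of 4 adjusted over the list alone. The call of miR-181c was lost without differentiated replicate 1 (adjusted p = 0.0511, limma). Of the fixed miR-29 list all 4 tested members rose, including miR-29a (1.05 ± 0.12) and miR-29c (0.65 ± 0.12), although the sign of miR-29a turned without scaling and that of miR-29c without scaling and on the authors' scale. Outside the list, chosen after their values were seen, the partner strand miR-29a* rose by 1.60 ± 0.13 and miR-29c*, not well above background in dedifferentiated cells, was at least 1.58-fold lower (adjusted p = 0.000614 and 0.00274, limma). The p53-responsive miR-34 group had 3 of 3 tested members higher: miR-34a (1.39 ± 0.19), miR-34b* (1.14 ± 0.18) and miR-34c-5p (0.49 ± 0.14); miR-34a had no call without scaling (0.19, adjusted p = 0.583, limma), the sign of miR-34b* turned without scaling and that of miR-34c-5p under each of the 4 other scalings. The call of miR-34c-5p was lost without differentiated replicate 2 or 3 or dedifferentiated replicate 2 (adjusted p = 0.0571, 0.0531 and 0.0509, limma).

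The let-7 family, whose levels typically rise as cells mature, mostly fell: 6 of 9 members were lower, with a median change of -0.69 (camera adjusted p = 0.0851). let-7g fell by 1.04 ± 0.15, let-7a by 0.69 ± 0.11 and let-7f by 0.69 ± 0.14. Over the alternatives the median of the list ranged from -1.89 to -0.0875 and the camera adjusted p from 2.66e-07 to 0.442. In the main scaling the list had an adjusted p = 0.614 with an estimated correlation. let-7i was called higher (0.34 ± 0.11) but had the opposite sign under 3 of the 4 other scalings, and its call was lost without differentiated replicate 1 or 2 or dedifferentiated replicate 2 (adjusted p = 0.0968, 0.09 and 0.0891, limma). The call of let-7f was lost without differentiated replicate 1 (adjusted p = 0.06). The epithelial miR-200 group, which restrains the repressors of E-cadherin, had 2 of 3 tested members lower, miR-200a (fell by 1.39 ± 0.46) and miR-200b (fell by 0.85 ± 0.19). miR-429 was not well above background on any dedifferentiated array, so its fitted change (-0.82 ± 0.29, adjusted p = 0.0508, limma) depends on the floor. Adjusted over the list alone all 3 were lower. The call of miR-200a was lost without any of the 3 differentiated replicates (adjusted p = 0.142, 0.144 and 0.143, limma) and without dedifferentiated replicate 3 (adjusted p = 0.0575), and that of miR-200b without differentiated replicate 1 or 3 (0.0713 and 0.0518). Of the fixed list of RPE-enriched miRNAs, 4 of 6 tested fell (miR-204, miR-211, miR-200a and miR-200b) and 2 rose (miR-221 and miR-222, the latter by 1.43 ± 0.21), and the list as a whole did not pass the group test (camera adjusted p = 0.644). miR-222 had no call on the authors' scale (0.59, adjusted p = 0.110) or without scaling (0.22, adjusted p = 0.464, limma).

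In miR-17-92 and its paralogs, 7 of 14 tested members were higher and 1, miR-363, was lower (camera adjusted p = 0.409), but of the 7 only miR-18a (2.19 ± 0.14) kept its sign under all 4 other scalings. miR-106b changed by 0.77 ± 0.13 and miR-17 by 0.37 ± 0.11, both called, while miR-19b (0.13 ± 0.12) and miR-20a (0.27 ± 0.12) were not; all 4 had a negative sign on the authors' scale. The call of miR-17 was lost without differentiated replicate 1 or 2 or dedifferentiated replicate 2 (adjusted p = 0.0644, 0.0578 and 0.0502, limma). miR-363 was detected on 1 of the 3 dedifferentiated arrays and lay at the floor on the other 2, so its fitted change (-4.28 ± 0.89) depends on the floor. In the miR-15/16 family 3 of 6 were higher and 1 was lower (adjusted p = 0.644): miR-424, miR-15b (1.38 ± 0.16, but 0.18 without scaling, adjusted p = 0.547) and miR-16 (0.43 ± 0.11, negative under 3 of the 4 other scalings) rose, miR-195 fell by 0.96 ± 0.12, and miR-15a (-0.25 ± 0.13) had no call. In miR-23/27/24, 3 of 5 were higher (adjusted p = 0.349), namely miR-27a (1.75 ± 0.18, but 0.55 without scaling, adjusted p = 0.113), miR-23a (1.03 ± 0.12, negative without scaling) and miR-24 (0.72 ± 0.12, negative under the authors' scaling and without scaling), against miR-27b at 0.27 ± 0.12 and miR-23b at -0.15 ± 0.10. The authors' scaling held the sum of miR-24 and miR-130a constant, so the sign of miR-24 there was tied to that of miR-130a. Of miR-130 and miR-301, 2 of 4 rose, miR-130a (0.95 ± 0.14, negative without scaling) and miR-130b (1.22 ± 0.13, but 0.016 without scaling, adjusted p = 0.958), 1 fell, miR-454 (by 0.47 ± 0.14), and miR-301a was at 0.03 ± 0.29. The miR-30 family split into 2 higher, including miR-30a (1.02 ± 0.12, negative without scaling), 3 lower, including miR-30b (fell by 0.69 ± 0.13) and miR-30c (fell by 0.63 ± 0.18), and 2 without a call, including miR-30d at -0.11 ± 0.11 (camera adjusted p = 0.644). Without differentiated replicate 1, 2 or 3 the calls of miR-454 (adjusted p = 0.124, 0.0927 and 0.0639) and miR-30c (0.129, 0.0728 and 0.0896) were lost, and without dedifferentiated replicate 3 as well (0.0697 and 0.0533, limma). miR-16 lost its call without differentiated replicate 2 or 3 (0.0577 and 0.0637) and miR-30b without replicate 1 (0.052). Of miR-99, miR-100, miR-125 and miR-10, 2 of 5 fell, miR-99a and miR-125b, and miR-100 (0.29 ± 0.19) and miR-125a-5p (0.31 ± 0.16) had no call (adjusted p = 0.644).

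Of the neural retina list, 3 of 6 tested fell (miR-9, miR-9* and miR-128, the last by 1.08 ± 0.16) and 3 rose (camera adjusted p = 0.644). Those that rose were miR-137, miR-96 and miR-7 (0.55 ± 0.19, with the opposite sign under all 4 other scalings). miR-96 was at least 7.40-fold higher under the main scaling and its detection limits (fitted 4.32-fold, log2 change 1.52 without scaling). The stromal, blood and endothelium, inflammation and C19MC lists had too few tested members for a group test. The stromal and smooth-muscle miRNAs miR-143 (0.43 ± 0.46) and miR-145 (0.34 ± 0.33) had no call and were the only 2 of the 8 list members tested. For blood and endothelium only miR-126 was tested, with a change of 0.14 ± 0.13 and no call. Of the inflammation list, 2 of 4 rose (miR-155, and miR-212 by 0.93 ± 0.19) and 1 fell (miR-146b-5p, by 1.00 ± 0.21, detected on 2 of the 3 dedifferentiated arrays). miR-132, not well above background on any dedifferentiated array, had a fitted change of -0.71 ± 0.62 and no call. The sign of miR-212 turned without scaling and its call was lost without differentiated replicate 3 (adjusted p = 0.053, limma). The call of miR-146b-5p was lost without differentiated replicate 1 or 3 (0.0638 and 0.0516). In the placental cluster C19MC only miR-512-3p was tested (fitted change 0.23 ± 0.12, no call), and it was not well above background on any dedifferentiated array. No member of the pluripotency, X-linked miR-506 to miR-514, or muscle and liver lists met the rule for testing, although 1 pluripotency member was detected on at least 1 array. By fry, which sets the members against no change and not against other miRNAs, the adjusted p was 0.00697 for neural retina, 0.294 for RPE-enriched, 0.000633 for TGF-beta responsive, 0.0056 for let-7, 0.0139 for miR-17-92 and 0.789 for miR-30. It was 0.00229 for miR-15/16, 0.0035 for miR-23/27/24 and 0.0456 for miR-99, miR-100, miR-125 and miR-10. Counts adjusted over the list alone equalled those over all miRNAs except where given above.

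**Figure D2:**
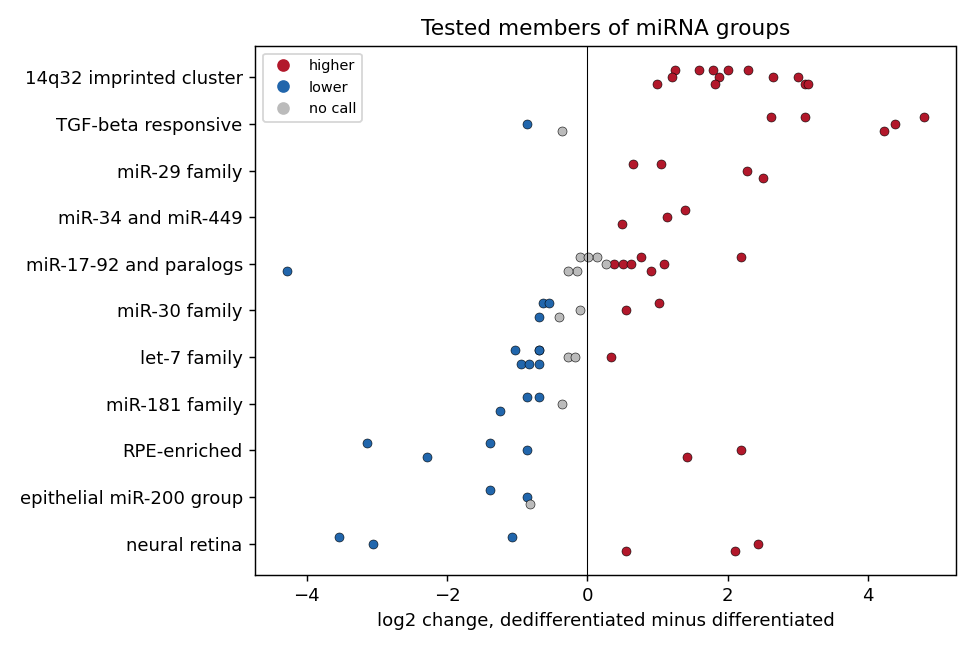
Log2 change (x axis, dedifferentiated minus differentiated) of each tested member of 11 miRNA lists (y axis), coloured by its call at an adjusted p of 0.05 in limma. All 13 tested members of the 14q32 cluster lie to the right of 0, 6 of 9 let-7 members were called lower, and the RPE-enriched and neural retina lists split. The signs of members near 0, such as miR-34c-5p, let-7i and miR-17, turn under other scalings, as does that of miR-432 of the 14q32 cluster without scaling.

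Over all 216 miRNAs tested, 83 were higher and 76 were lower in dedifferentiated cells. Of these, 60 and 39 changed at least 2-fold, 22 and 10 at least 4-fold, and 14 and 23 were not well above background on any array of the other group. The split depended on the scaling: the median change was 0.00 in the main scaling, -0.81 on the authors' scale, -0.57 with the percentile over all human miRNAs, -0.20 after quantile normalization and -1.05 without scaling. The corresponding numbers of higher and lower miRNAs were 46 and 121, 55 and 109, 62 and 94, and 27 and 136, so that 52.2% of calls were higher in the main scaling, against 27.5%, 33.5%, 39.7% and 16.6%. Of the main calls, 74 of the 76 lower but 27 of the 83 higher miRNAs held under all 5 scalings. As the 4 others lower the median change, this says little about the lower ones. The number of lower miRNAs was 44 without differentiated replicate 1 and 46 without differentiated replicate 3. Without dedifferentiated replicate 2, which stood apart, 1 dedifferentiated RNA sample remained, and the median log2 change was 0.062.

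The partially differentiated sample lay between the 2 group means for most called miRNAs. Against differentiated cells, 47 miRNAs were higher and 17 lower in this sample, assuming that it varied like the other groups. The total of 64 depended on the processing: it was 5 with normexp, 7 with a floor 4 times higher, 20 without a filter, 34 without scaling and 37 with a 2-fold change required. miR-31* was 2.56 higher on the log2 scale (adjusted p = 0.00263), miR-376a 2.71 (0.0131), miR-31 2.23 (0.00559) and miR-21 1.72 (0.00781, all adjusted p from limma). miR-9 fell by 1.94 on the log2 scale, at -4.24 against -2.30 in differentiated cells (adjusted p = 0.00352). miR-204 and miR-211 were at 6.17 and 3.85, against 6.63 and 4.33, with no call (adjusted p = 0.687 and 0.787). miR-200a, at -2.45 against -2.49, had no call either (adjusted p = 0.966). miR-145 and miR-143 were 1.53 and 1.72 above differentiated cells, also without a call (adjusted p = 0.0513 and 0.0889).

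For the 101 called miRNAs detected on all arrays of both groups, the position of the partially differentiated sample on the path from the differentiated mean (0) to the dedifferentiated mean (1) had a median of 0.41 (quartiles 0.20 and 0.71), and 84 of the 101 lay between the means. The median was 0.274 without scaling and 0.156 with scaling by the hur control probes. The same position computed for each differentiated sample had an SD of 0.050. Of the 64 calls against differentiated cells, 46 higher and 15 lower ones were also called in that direction in dedifferentiated cells, where independent lists of these sizes would share 18.1 and 5.98. Both comparisons use the same differentiated samples: changes correlated at 0.87 across miRNAs, which are not independent replicates, against 0.34 in simulations without any change, and their covariance was 1.09 against 0.027, so part of the overlap may come from the shared samples. Against the partially differentiated sample, dedifferentiated cells had 6 miRNAs higher and 2 lower. That count was 25 without dedifferentiated replicate 3, 2 without differentiated replicate 1, and 0 without differentiated replicate 2 or 3 (limma, with 69 and 59 at an unadjusted p under 0.05). Without dedifferentiated replicate 2 each side of this comparison holds 1 RNA sample, so the spread would come from the differentiated samples alone. The count of 64 against differentiated cells was 38, 36 and 18 without differentiated replicate 1, 2 and 3.

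**Figure D3:**
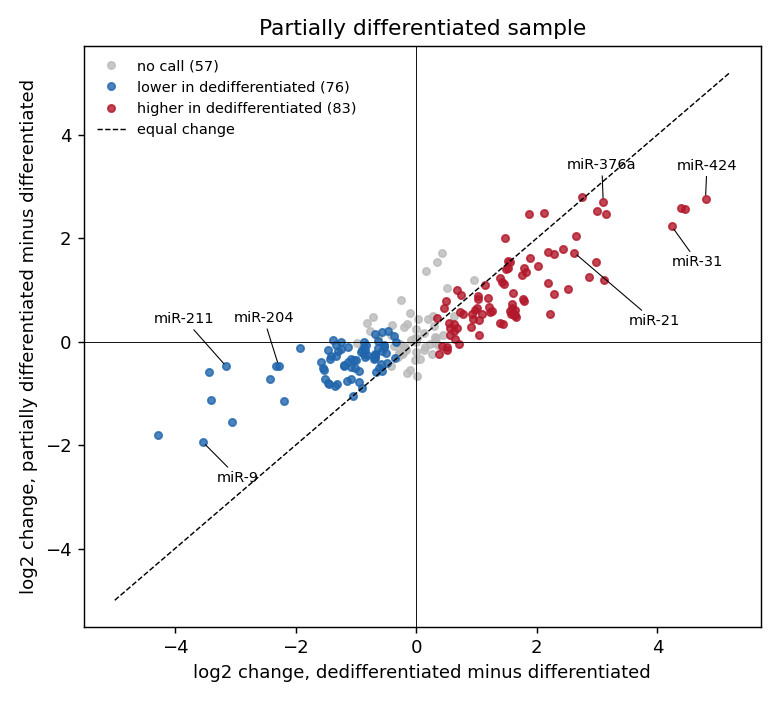
Log2 change of each of the 216 tested miRNAs in the partially differentiated sample (y axis, minus differentiated) against that in dedifferentiated cells (x axis, minus differentiated), coloured by the call for dedifferentiated cells; the dashed line marks equal change. Points lie mostly between the horizontal axis and the dashed line, with a median position of 0.41 over the 101 called miRNAs detected on all arrays of both groups.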

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

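The tests in this part were chosen after the results had been seen, except the splits of the samples.

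Signal appeared outside the main measurement: 3 of the 76 viral miRNA probe sets were well above background on every array, and 5 on at least 1 array. No sample without RNA was analysed here, and probe signal alone does not show that the viral sequences were present.

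Total human miRNA signal was 2.62-fold lower on the dedifferentiated than on the differentiated arrays (log2 change -1.39). A weaker hybridisation or scan of those arrays could lower all signals, and the 5 control probe sets named hur, whose target is not given in the sources used here, did fall by 0.74 on the log2 scale. The ratio of total to hur signal still changed by -0.648, with no overlap and SDs of 0.046 and 0.37 in differentiated and dedifferentiated samples, so this leaves part of the fall unexplained. A few bright miRNAs such as miR-204 do not carry it alone: the median unscaled change of all tested miRNAs was -1.05, and the total without the 10 brightest miRNAs changed by -0.97. The 2 arrays of dedifferentiated RNA 1, in different slide rows, differed by 0.447 in hur signal and 0.405 in total signal on the log2 scale. Signal thus varied by that much between arrays of the same RNA, so part of the fall can come from the arrays. A lower miRNA content of the dedifferentiated RNA stays open as an untested biological explanation.

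Dedifferentiated sample 2 lay between the other dedifferentiated RNA and the differentiated samples for many miRNAs that fell. The data argue against the slide row as the cause, as far as 1 pair of arrays can show, and the place within a row was not examined. The technical replicate of sample 1 lay in the same slide row as sample 2. Over the 42 lower miRNAs detected on every array of both groups, the replicate's median shift from the first array of sample 1 was 0.0151 (quartiles -0.053 and 0.049). That of sample 2 was 0.46 (quartiles 0.27 and 0.76). Carry-over of differentiated cells would give 1 common share of differentiated RNA, and the share implied by 27 such miRNAs that fell at least 2-fold in sample 1 had a median of 0.28 (quartiles 0.24 and 0.33), against 0.185 (quartiles -0.047 and 0.34) for the 62 that rose at least 2-fold. The quartiles overlap, so carry-over and a less complete dedifferentiation of that culture cannot be told apart. Against a single share speak miR-204, which needs 0.325, beside miR-9, whose undetected level allows at most 0.166, and the 17 of 62 risen miRNAs, such as miR-29b and miR-630, that were higher in sample 2 than in sample 1.

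Of the 83 miRNAs called higher, 56 lost the call under at least 1 other scaling, and 29 of these were dim (a mean level below -3 on the log2 scale). A constant probe signal that is multiplied when an array is scaled up is a candidate explanation for the dim ones. The 3 viral probe sets with signal on every array rose after scaling by a mean of 0.96 (SD 0.64), within the range of the dim miRNAs (0.49 to 1.79, median 1.22), while 11 of the 29 rose by more than any of the 3. Unscaled, the dim miRNAs had a median change of 0.016. A true rise of some of these miRNAs stays open.

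The real grouping gave 159 called miRNAs and the highest of the other splits of the 5 samples into 3 and 2 gave 0 (limma; 9 at most at an unadjusted p under 0.05, against 162), with 1 of the 10 splits reaching the real value; 10 splits are too few for a share under 0.05.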

How the results depend on the processing

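The 3 alternatives chosen after seeing the data were normexp on the median signals, the first slide row alone and scaling by the hur control probes. Not run were normexp on mean signals (the files hold median signals), the RNA as a random block (duplicateCorrelation could not be estimated from 1 duplicated RNA) and the slide as a block (1 slide). Leaving out 1 array at a time, including settings in which the lone dedifferentiated sample is assumed to vary like the other groups, gave 70 to 90 higher and 44 to 81 lower miRNAs, 18 to 75 and 0 to 110 calls for the partially differentiated sample against differentiated and dedifferentiated cells, positions of 0.368 to 0.526, and 1 list in each case. Weak signal over background limits the dim miRNAs: with a floor 4 times higher, 39 were lower, 7 differed between partially differentiated and differentiated cells, and the list past the threshold was let-7 in place of 14q32.

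Scaling moves all changes of an array together and so shifts both counts. With the percentile over all human miRNAs, 55 were higher, the position was 0.531 and 2 lists passed (14q32 and TGF-beta responsive). Without scaling, 27 were higher and 136 lower, 34 and 97 calls involved the partially differentiated sample, its position was 0.274 and the same 2 lists passed. On the authors' scale, 46 were higher and 121 lower, the position was 0.468 and the same 2 lists passed. With hur scaling, 67 differed between dedifferentiated and partially differentiated cells, the position was 0.156 and the same 2 lists passed.

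Normexp with quantile normalization gave 8 higher, 12 lower, 5 calls for the partially differentiated against differentiated cells and the same 2 lists; the cause was not tested. Without a filter, where 719 miRNAs were tested, 33 were lower, 20 and 16 calls involved the partially differentiated sample, the position was 0.526 and 3 lists passed (14q32, let-7 and miR-30); with miRNAs detected on at least 1 array, 2 lists passed (14q32 and let-7). The 8 miRNAs differing between dedifferentiated and partially differentiated cells were the least stable: 47 after quantile normalization, 16 with total gene signals, 25 with the brightest probe, 27 with the mean over probes, 24 with detection on at least 1 array, 13 with the detection flag per miRNA, 89 with 3 independent arrays, 36 with trend and robust moderation and 79 at an adjusted p under 0.10; the cause was not tested. Requiring 2-fold changes left 39 lower, 37 against differentiated cells and a position of 0.484. With the replicate number as a block, 62 were higher, 29 lower, and 0 and 0 calls involved the partially differentiated sample (limma; 57 and 57 at an unadjusted p under 0.05), whose position was 0.571. The deviations of same-numbered samples correlated at 0.149 and 0.0688 in the 2 shared numbers. These are too few to show or exclude pairing, and the labels give only a shared number. The first slide row alone compared the differentiated arrays with dedifferentiated replicate 1 only, and gave a median log2 change of 0.163.

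Of the 80 named miRNAs, these called changes turned sign under another scaling, which (except quantile normalization) shifts all changes of an array together: without scaling miR-17 (-0.827), miR-106b (-0.429), let-7i (-0.859), miR-30a (-0.179), miR-29a (-0.153), miR-29c (-0.55), miR-34b* (-0.0607), miR-34c-5p (-0.712), miR-212 (-0.275), miR-16 (-0.772), miR-23a (-0.173), miR-24 (-0.479) and miR-130a (-0.256). On the authors' scale these were miR-17 (-0.463), miR-106b (-0.0649), let-7i (-0.495), miR-29c (-0.186), miR-34c-5p (-0.348), miR-16 (-0.408) and miR-24 (-0.115, tied to miR-130a, as their sum is constant there). With the percentile over all human miRNAs they were miR-17 (-0.238), let-7i (-0.271), miR-34c-5p (-0.124) and miR-16 (-0.184), after quantile normalization miR-34c-5p (-0.162; the cause was not tested), and with hur scaling miR-17 (-0.0881), let-7i (-0.121) and miR-16 (-0.0335). With normexp miR-191* turned sign (-0.147), and the cause was not tested. Calls were lost without a sign change for 50 named miRNAs with normexp, 27 without a filter, 23 with the block, and 17, 12 and 14 without differentiated replicate 1, 2 and 3.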

Other observations

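The tests of neighbouring genes, of precursor strands and of positions were all chosen after the changes of single miRNAs had been seen.

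miRNAs encoded close together changed alike. Over 102 pairs of tested miRNAs with different numbers whose genes lie within 10 kb in the RefSeq table, log2 changes differed by 0.846 on average, against 1.62 for shuffled changes (permutation p = 1e-05, the smallest that 100000 permutations can give). Without pairs on chromosome 14, 81 pairs remained with a mean difference of 0.84 (permutation p = 5e-05). Among the 142 miRNAs detected on all arrays of both groups, 52 pairs differed by 0.716, against 1.43 (permutation p = 0.00015). Both members were called in the same direction in 41 pairs, such as miR-221 and miR-222 (2.19 and 1.43), let-7c and miR-99a (-0.95 and -2.19) or let-7f and miR-98 (-0.69 and -0.83), and in opposite directions in 1 pair, miR-363 (-4.28, dependent on the floor) and miR-18b (0.51), whose sign turns under the other scalings. Shared transcription of neighbouring miRNA genes would give this pattern, with limits. Pairs share members, some miRNAs have copies elsewhere, and miR-363 did not follow its cluster. Some neighbours, such as let-7f and miR-98, belong to the same family and can share probe signal, which could also make them change alike.

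miRNAs named as strands of 1 precursor or of its gene copies also changed together, as shared supply of a precursor's 2 strands would give. Over 37 pairs the mean difference was 0.709, against 1.62 for shuffled changes (permutation p = 1e-05, the smallest possible). Pairs were matched by name. They include miR-181a-2* with miR-181a*, from 2 gene copies, and set miR-24 and miR-29b, with 2 gene copies each, against a strand of 1 copy. Among the miRNAs detected on all arrays of both groups, 15 pairs differed by 0.518, against 1.43 (permutation p = 8e-05). 16 pairs were called in the same direction, such as miR-31 and miR-31* (4.24 and 4.45). 3 pairs were called in opposite directions: let-7f (-0.69) with let-7f-1* (at least 2.97-fold higher), miR-181a (-0.86) with miR-181a-2* (0.62), and miR-29c (0.65) with miR-29c* (at least 1.58-fold lower). These depended on the scaling: without scaling let-7f-1* had no call (adjusted p = 0.171, limma), and on the authors' scale and without scaling miR-181a-2* (-0.21 and -0.58) and miR-29c (-0.19 and -0.55) turned sign.

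In the partially differentiated sample, miRNAs that rise with dedifferentiation had a median position of 0.58 (59 miRNAs) and those that fall a median of 0.21 (42 miRNAs). The difference of 0.37 was beyond shuffled labels (permutation p = 1e-05, adjusted over the 5 scalings 2e-05). Under the other scalings it was 0.60 without scaling, 0.11 on the authors' scale, 0.11 after quantile normalization and 0.0785 with the percentile over all human miRNAs, and the last 3 were within shuffled labels (permutation p = 0.084, 0.254 and 0.281). The shuffled labels were those of miRNAs within 1 sample, which had a mixed epithelial and fibroblastic look. On the log2 scale a plain mixture of both cell states also places rises further along than falls. The shuffling cannot separate such a mixture from an order of changes. An order in time of gains and losses was therefore not tested, and a scaling offset of that array cannot be excluded.

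Several array entries that are now read as fragments of other RNAs, chosen here after their values were seen, changed as well. miR-923, withdrawn as a piece of ribosomal RNA, rose by 1.52 ± 0.28 (0.68 on the authors' scale, adjusted p = 0.129, limma) and was highest in dedifferentiated sample 2 and the partially differentiated sample (2.37 and 2.03, against 1.60 and 1.64 on the arrays of dedifferentiated RNA 1). miR-886-3p, now known as part of a vault RNA, rose by 1.80 ± 0.14, and miR-768-3p, part of a small nucleolar RNA, fell by 1.01 ± 0.11.

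Compared with differentiated cells, 3 miRNAs were called in the partially differentiated sample without a call in dedifferentiated cells: miR-17* (-0.60), miR-20b (-0.55) and miR-30d (0.55). They were not shown to differ between the 2 states: for dedifferentiated against partially differentiated cells the adjusted p was 0.108, 0.0956 and 0.0561 (limma, with the lone sample assumed to vary like the other groups).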
